A study of Mus musculus with 26 samples.

How the data were processed

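The series holds 26 samples from C57BL/6 mice, 18 of fecal DNA and 8 of ileal RNA, placed in groups by their labels. For feces, DNA was extracted with a bead-beating spin kit and bacterial 16S rRNA genes were amplified and sequenced, per the labels' protocols. The fecal table holds whole-number counts of reads per operational taxonomic unit (OTU) and sample as deposited by the authors, with a Greengenes-style lineage for each OTU, per the file headers. The clustering tool, its identity threshold and the reference version are not given in the sources used here. Of the OTU names, 1235 are reference identifiers, which hold 98.6% of counts, and 397 are read names, and the lowest OTU total is 2 counts. Epithelium was collected by laser capture microdissection and libraries were made with a TruSeq RNA kit, per the labels' protocols. Both RNA tables hold FPKM (fragments scaled to transcript length and sequencing depth) per library as deposited by the authors, per the file headers. TopHat, Cuffdiff and the builds mm10 and GRCm38 are named in the submitters' processing notes, without versions, and whether counting used strand is not given in the sources used here. The RNA tables were held in part: 22 genes with values from each were analysed here, and 24 further per-library columns (such as confidence limits and status) were not used. Depth behind the FPKM values is unknown, so no interval from counting error is given for them.

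Fecal totals ran from 63571 to 91972 counts, so that a floor of 3 counts in a sample is a share of 0.00326% to 0.00472%. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Of all counts 48.2% had no genus name and were kept under the lowest named rank as unclassified, and 92 OTUs with 316 counts (0.0228%) had no phylum. Shares are percentages of all counts in a sample and say nothing of absolute numbers of bacteria.

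The main tests, alternatives and named items were fixed before the data were examined. Counts per genus and per OTU were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling) in 1 model with 4 groups, keeping features with a count in at least 4 samples and a total of at least 20, which left 63 genera and 703 OTUs. Benjamini-Hochberg adjusted p under 0.05 was called a change, and all tests were two-sided unless stated. Shares of 7 phyla and 22 families with a mean of at least 1% in any group, the Shannon index (natural log) and the number of observed OTUs after rarefaction to 63571 counts were compared by exact permutation of sample labels, within genotype for the diet comparison over both genotypes. Community profiles were compared by exact permutational multivariate analysis of variance on Bray-Curtis distances of OTU shares. FPKM values were tested with limma 3.58.1 (empirical Bayes with trend) on log2(FPKM + 1), which understates changes of low genes, for 19 genes with a mean of at least 1 FPKM. Each RNA table was tested on its own, since they were normalized separately. Gene symbols were matched to the mouse RefSeq table, 22 of 22 in each RNA table, 15 of them through synonyms, and coordinates are those of the deposited tables (mm10), counted from 1.

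Named items were Snhg9 (not analysed here), up to 10 genes per direction among those called, members of fixed gene lists, all phyla, the 10 largest families, up to 10 genera per direction with the smallest adjusted p, and 6 fixed taxon lists. Of the fixed gene lists only the one of non-coding RNAs, which takes in symbols ending in Rik, had members among the analysed genes, and 0 markers of other cell types were among them. The 7 genes at an unadjusted p under 0.05 in the epithelium, and 4 of these in the ileum, were named after their values were seen.

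Alternatives were DESeq2 1.42.0 with poscounts size factors, total-count scaling, limma on centred log-ratios (pseudocount 0.5), other filters (none, or a total of at least 100), fits of the compared groups only, sample numbers as a block, other diversity indices and distances, leaving out each sample in turn, and for RNA pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 FPKM and quantile normalization. Drawing counts to the smallest library, removing S24-7 from the totals and leaving out samples for the OTUs aligned to the mouse genome were added after seeing the data. The tests were tested on simulated data. For edgeR, each feature had the same mean share in all groups before changes were added, taken over the samples of both diets. Features were drawn independently, so a rise of one did not lower the others. Recovery and false calls are thus a rough guide to the real comparisons. With 63 genera, edgeR recovered 0%, 20%, 80% and 60% of genera changed 2-, 4-, 8- and 16-fold between genotypes on high-fat diet, and 33.3%, 80%, 100% and 80% between diets, with 0 false calls, on 5 or 6 genera per fold, too few to rank the folds. With 665 OTUs it recovered 2.13% of those changed 16-fold between genotypes on high-fat diet. With 661 OTUs it recovered 2.17%, 14.3%, 51.2% and 82.9% of those changed 2-, 4-, 8- and 16-fold between diets, and 7 of 71 calls were false. For limma with 22 genes in the transgenic against wild-type ileum comparison, 100% of 4-fold changes were recovered, with 33 false calls over 100 simulations. The exact multivariate test called 6% of 200 simulations without a difference and 100% of those with a large difference in many taxa. The spread between these simulated samples was chosen and not fitted to the fecal samples. The 100% therefore says nothing of the power to see smaller differences, such as those between genotypes. OTU sequences were aligned to the mouse genome GRCm38.p6 with minimap2 2.31-r1302 (k of 13, w of 5), keeping at least 90% identity over at least 80% of the sequence. Other steps used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.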

Results

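The series compared mice with and without a gut microbiota, and mice with and without an added copy of Snhg9, a long non-coding RNA, under the control of the villin promoter, which is active in intestinal epithelium. Fecal bacterial 16S rRNA genes were counted in 18 samples from C57BL/6 mice, with 4 wild-type and 5 Villin-Snhg9 transgenic samples on chow and the same numbers on a high-fat diet. Ileal RNA was measured in 8 libraries, which were 2 conventional and 2 germ-free libraries of laser-captured epithelium and 2 transgenic and 2 wild-type libraries of whole ileum. The fecal table held 1632 operational taxonomic units (OTUs, clusters of similar 16S sequences) in 9 phyla. Total counts were 66373 ± 3243 (SD, n = 4) in wild-type and 74277 ± 3976 (SD, n = 5) in transgenic samples on chow. On high-fat diet they were 82578 ± 9524 (SD, n = 4) and 84359 ± 6539 (SD, n = 5). Of each RNA table, 22 genes were analysed here, so both RNA comparisons describe those genes and not the transcriptome. Snhg9 itself was not analysed here. The labels do not say which samples came from separate animals, and p-values measure the spread between these samples.

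The diet comparison asked how fecal bacteria differed after the switch from chow to high-fat diet. In such a design the time of collection and the age of the mice may differ along with diet. They were not separated from diet here. On high-fat diet the S24-7 family of Bacteroidetes, the most abundant family on chow, was much lower, and so was Sutterella, and the mean of Akkermansia, a mucin-degrading genus, was lower. Firmicutes took larger shares, as did Desulfovibrionaceae, which include sulfate-reducing bacteria. The mean share of Helicobacteraceae was higher. Unclassified S24-7 made up 36.5% ± 2.83 of counts on chow (SD, n = 9) and 8.44% ± 3.80 on high-fat diet (SD, n = 9), 4.32-fold lower. Unclassified Desulfovibrionaceae went from 0.00386% ± 0.0035 to 6.10% ± 2.42 (SD, n = 9 each). Sutterella made up 2.24% ± 0.802 on chow and had 0 counts in all 9 high-fat samples, at least 619-fold lower against the mean floor of 3 counts per sample.

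Among phyla, Firmicutes rose by 22.4 percentage points and Proteobacteria by 9.43 points, averaged over both genotypes. Bacteroidetes fell by 25.3 points and Verrucomicrobia, represented by Akkermansia, fell by 6.25 points. Exact permutation tests within genotype gave adjusted p-values of 0.000397 for Firmicutes and Bacteroidetes, 0.000794 for Verrucomicrobia and 0.00119 for Proteobacteria (two-sided, 7 phyla). The unadjusted p of 0.000113 behind the first of these is the smallest the 17640 arrangements can give. These p-values treat the samples as independent, which the labels do not settle. Proteobacteria differed by 5.37 points in wild-type (exact permutation adjusted p = 0.3) and by 13.5 points in transgenic samples (adjusted p = 0.0139). Deferribacteres differed by 1.40 points on average (adjusted p = 0.0141), which was 0.0343 points in wild-type (adjusted p = 0.914) and 2.78 points in transgenic samples (adjusted p = 0.0139), and edgeR did not call its genus Mucispirillum over both genotypes (adjusted p = 0.192). Actinobacteria fell by 1.46 points (adjusted p = 0.0274), a call that ended without any 1 of 4 wild-type samples, number 2 or 3 on chow or number 2 or 4 on high-fat diet (adjusted p of 0.054 to 0.0631). TM7 differed by 0.0594 points (adjusted p = 0.909). Cyanobacteria, assigned to the gut order YS2 apart from 1 chloroplast OTU with 2 counts, and Tenericutes lay below 1% in every group and were not tested as shares.

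**Figure D1:**
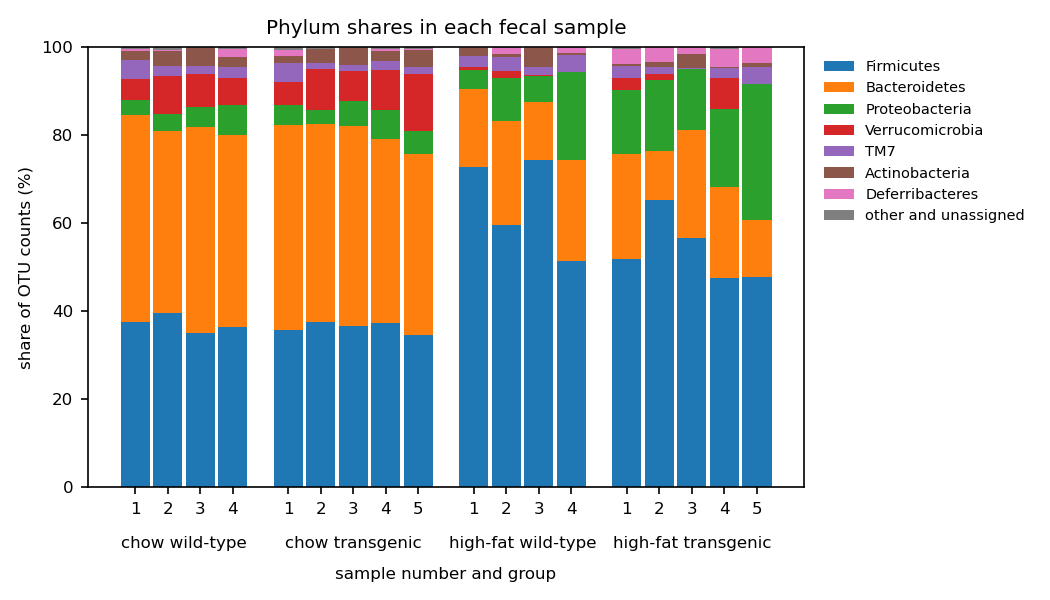
Share of OTU counts (%, vertical axis from 0 to 100) taken by each phylum in each of the 18 fecal samples, 1 bar per sample, grouped by diet and genotype. Firmicutes averaged 37.1% and 36.4% on chow in wild-type and transgenic samples, and 64.5% and 53.8% on high-fat diet.

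Of 22 families, 14 changed with diet, 9 higher and 5 lower. The S24-7 family fell by 27.8 points and unclassified Clostridiales rose by 13.6 points, both at an adjusted p of 0.000356 in the exact permutation test. Helicobacteraceae rose by 6.58 points (adjusted p = 0.00136), Ruminococcaceae by 5.65 (0.000624), Desulfovibrionaceae by 5.36 (0.000356) and Lachnospiraceae by 3.93 (0.000356). For Helicobacteraceae the difference was 4.18 points in wild-type (exact permutation adjusted p = 0.251) and 8.97 points in transgenic samples (adjusted p = 0.0175). Lactobacillaceae differed by 1.12 points (adjusted p = 0.873), an average of 7.78 points in wild-type (adjusted p = 0.444) and -5.53 points in transgenic samples (adjusted p = 0.298), Erysipelotrichaceae by -4.31 points (adjusted p = 0.0945) and F16 by 0.0594 points (adjusted p = 0.932). Within wild-type samples 0 families and 0 phyla passed after adjustment. There, 4 samples against 4 allow no exact p under 0.0286, and only 10 families and 3 phyla reached it. This gave adjusted p-values of 0.0629 and 0.0667 at best. At an unadjusted p under 0.05 in that exact test, 10 families and 3 phyla differed in wild-type samples. In transgenic samples 12 families and 5 phyla passed, but 0 did with sample numbers as a block, where 5 pairs are too few for the exact test to pass.

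At the genus level, edgeR's quasi-likelihood test called 39 of 63 genera between diets, 21 higher and 18 lower on high-fat diet. Besides unclassified Desulfovibrionaceae (log2 fold 9.88 ± 0.72 SE, adjusted p = 3.85e-09), Roseburia, a butyrate producer, and Flexispira, a relative of Helicobacter, rose from 1 and 2 counts over the 9 chow samples to shares of 0.891% ± 0.662 and 0.516% ± 0.369 (SD, n = 9; edgeR adjusted p = 1.69e-07 and 8.51e-08). Lactococcus, a dairy lactic acid bacterium, had 0 counts in the 9 chow samples and 0.853% ± 0.372 on high-fat diet (SD, n = 9), at least 200-fold higher, and Streptococcus rose from 1 count to 0.0289% ± 0.0183 (edgeR adjusted p = 8.17e-06). Prevotella fell from 0.452% ± 0.375 to 2 counts over the 9 high-fat samples (edgeR adjusted p = 2.96e-06). Candidatus Arthromitus, the segmented filamentous bacteria that attach to ileal epithelium, fell from 0.114% ± 0.0591 to 0.000764% ± 0.000999 (log2 fold -7.65 ± 1.03 SE, edgeR adjusted p = 5.28e-06). Unclassified YS2, RF39, RF32 and Prevotellaceae, Coprobacillus, Jeotgalicoccus and rc4-4 fell as well. Jeotgalicoccus and rc4-4 held only 30 and 40 counts on chow and 0 on high-fat diet, at least 1.34- and 1.89-fold lower against the mean floor. The rc4-4 mean on chow was 0.00685%, and 0.00318% without wild-type sample 2. Coprococcus, [Ruminococcus], Christensenella, unclassified Bacteroidales and unclassified Peptococcaceae rose.

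In the list of taxa associated with high-fat diet, 3 of 10 measured genera rose, 1 fell and 6 did not pass; 4 were called when adjusted over the list alone. Bilophila, which grows on bile-acid taurine, rose from 0.00567% ± 0.0126 to 0.0542% ± 0.0293, and unclassified Peptostreptococcaceae had 0 counts on chow and 0.382% ± 0.717 on high-fat diet (SD, n = 9). The Peptostreptococcaceae mean rests on few samples, with 1.98% in wild-type sample 3 and 0.183% as the mean without it, and the Bilophila mean on chow was 0.00152% without transgenic sample 1. Desulfovibrio fell from 0.849% ± 0.867 to 0.24% ± 0.0868, opposite to the unclassified members of its family. Lactobacillus lay at 15.0% ± 3.01 and 15.4% ± 12.5, and Allobaculum at 10.4% ± 2.69 and 6.24% ± 5.62, with edgeR adjusted p-values of 0.44 and 0.117. Allobaculum became called in 6 alternatives and kept its side of the threshold in 20. Of 5 genera on the butyrate and clostridia list, Roseburia and Oscillospira rose, Clostridium fell and 2 did not pass, with 3 called when adjusted over the list alone. Of 7 genera on the Bacteroidetes list, Odoribacter rose, Alistipes and both Prevotella labels fell and 3 did not pass, with 4 called when adjusted over the list alone. Alistipes held 22 counts on chow and 7 on high-fat diet, means of 0.00338% and 0.000925%, near or under the floor of 3 counts in a sample, and its call ended without wild-type chow sample 4 (adjusted p = 1.00), with DESeq2 (0.117) and with no filter (0.083). The Odoribacter call ended without any 1 of 7 samples, numbers 1 of all 4 groups, wild-type 2 and 4 and transgenic 4 on high-fat diet (adjusted p of 0.0503 to 0.0799). Its log2 fold was 1.17 to 1.37 there, against 1.35 with all samples. The Clostridium call ended with no filter (0.0652). Bacteroides lay at 2.12% ± 1.29 and 2.24% ± 1.63. Both measured genera of the mucin list, Akkermansia and S24-7, fell, both of the diet DNA list, Lactococcus and Streptococcus, rose, and on the epithelium-adherent list Helicobacter rose and Candidatus Arthromitus fell. Each of these 3 lists had 2 called when adjusted over the list alone. The Akkermansia call (log2 fold -3.50 ± 1.22 SE, edgeR adjusted p = 0.0187) ended with scaling to total counts (adjusted p = 0.0535) and with no filter (0.0554), and edgeR called it in neither genotype alone (adjusted p = 0.0932 in wild-type and 0.116 in transgenic samples), while the exact permutation test of its family share gave an adjusted p of 0.000748. Its share in transgenic sample 4 on high-fat diet, 7.19%, lay within the chow range of 4.77% to 12.9%, and the high-fat mean was 1.56% with and 0.860% without that sample.

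**Figure D2:**
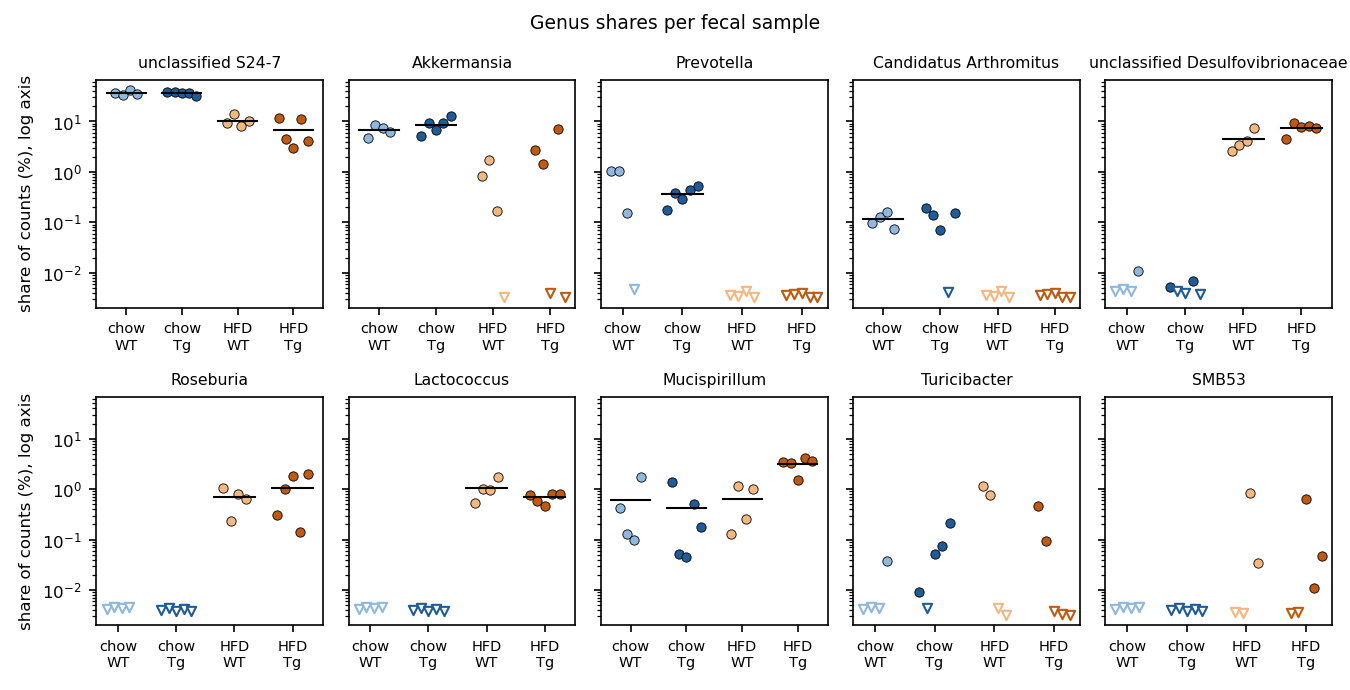
Share of counts (%, log axis) of 10 genera in each fecal sample, by diet and genotype (WT wild-type, Tg transgenic, HFD high-fat diet); bars mark group means where all samples have over 3 counts, and open triangles mark samples with 3 or fewer counts at their floor of 3 counts. Mucispirillum averaged 0.633% in wild-type and 3.21% in transgenic samples on high-fat diet, and the panel for SMB53 shows counts in 5 of 9 high-fat samples and in 0 of 9 chow samples.

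Within genotypes edgeR called 21 genera in wild-type (9 higher, 12 lower) and 31 in transgenic samples (18 higher, 13 lower). Fits of only the compared groups turned this order round, with 31 in wild-type (17 higher, 14 lower) and 23 in transgenic samples (15 higher, 8 lower). These comparisons have separate controls, and 20 genera were called in both, all in the same direction, where independent lists would share 10.3. With scaling to total counts in place of TMM the splits were 15 higher and 12 lower in wild-type and 23 higher and 8 lower in transgenic samples. Total scaling shifted the median log2 fold of all genera by 0.54 for diet, 0.47 and 0.64 for diet within wild-type and transgenic samples, -0.15 for genotype on chow and 0.20 for the interaction, so fold changes are relative to the scaling; 0 called genera changed sign. Of 703 OTUs tested, 527 were called between diets, 268 higher and 259 lower. This balance depended on the filter, with 275 higher and 367 lower with none and 192 higher and 137 lower at a total of at least 100 counts; in simulated OTU counts, 7 of 71 calls between diets were false.

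Profiles separated by diet along the first principal coordinate, which held 64.6% of the variation. Mean Bray-Curtis distance was 0.693 between diets in wild-type samples, against 0.268 among chow and 0.385 among high-fat wild-type samples. Diet took 69.8% of the variation in wild-type (exact permutation p of the multivariate analysis of variance = 0.0286, the smallest that 70 splits allow) and 66.0% in transgenic samples (p = 0.00794, the smallest that 252 splits allow). Diversity within samples did not pass a test. The Shannon index was 3.77 ± 0.236 (SD, n = 4) and 3.77 ± 0.262 (SD, n = 5) on chow in wild-type and transgenic samples, and 3.89 ± 0.294 and 3.96 ± 0.280 on high-fat diet. Its mean difference between diets was 0.152 (exact permutation p = 0.236, two-sided), and that of OTU number at 63571 counts per sample was 23.6 (exact permutation p = 0.540, for observed OTUs).

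**Figure D3:**
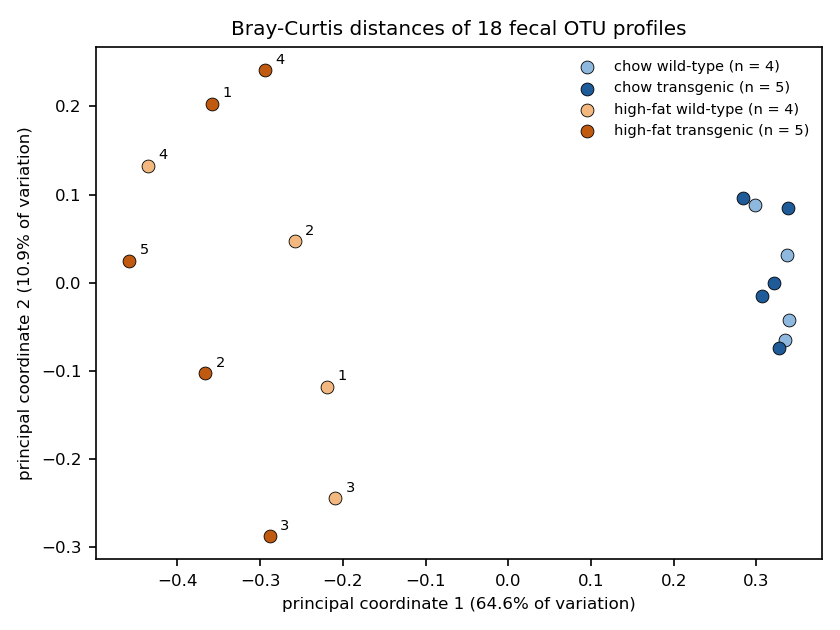
Principal coordinates of Bray-Curtis distances between 18 OTU profiles, 1 point per sample, with high-fat samples numbered; axis 1 holds 64.6% and axis 2 holds 10.9% of the variation. Chow samples of both genotypes lie together on the right, and high-fat samples lie on the left and spread along axis 2.

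The genotype comparison asked whether the transgene was accompanied by another fecal community. On chow S24-7 was at 36.7% ± 3.46 (SD, n = 4) in wild-type and 36.2% ± 2.62 (SD, n = 5) in transgenic samples and Akkermansia was at 6.78% ± 1.71 and 8.66% ± 2.96. On high-fat diet Mucispirillum, a mucus-dwelling genus and the Deferribacteres genus here, was at 3.21% ± 0.992 (SD, n = 5) in transgenic and 0.633% ± 0.514 (SD, n = 4) in wild-type samples. Each of the 5 transgenic samples lay above each of the 4 wild-type samples, an exact permutation p of 0.0159 that became 0.111 over 7 phyla and 0.349 over 22 families. In edgeR its log2 fold was 2.40 ± 0.93 SE (adjusted p = 0.566).

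edgeR called 0 of 63 genera between genotypes on chow (1 at an unadjusted p under 0.05) and 0 on high-fat diet (3 unadjusted). DESeq2 called 0 genera on each diet, with 1 and 6 unadjusted, and limma on centred log-ratios called 0, with 2 and 3 unadjusted. Each of the 6 fixed taxon lists had 0 genera called between genotypes on either diet, also when adjusted over the list alone. At the OTU level edgeR called 0 of 703 on chow (23 unadjusted) and 0 on high-fat diet (45 unadjusted), where DESeq2 called 0 on chow (13 unadjusted) and 8 on high-fat diet (48 unadjusted). Genotype took 9.79% of Bray-Curtis variation on chow (exact permutation p = 0.595) and 17.3% on high-fat diet (p = 0.230). The genotype difference in the Shannon index was -0.00343 on chow and 0.0761 on high-fat diet (exact permutation p = 0.992 and 0.706, two-sided). For the difference of the diet change between genotypes edgeR called 0 of 63 genera (1 unadjusted), and DESeq2 called 0 with 2 unadjusted. In simulated counts of this size, with 5 genera per fold, 20% of genera set 4-fold apart between genotypes on high-fat diet were called, 80% of those set 8-fold apart and 60% of those set 16-fold apart. Of simulated OTUs, 0% of those set 8-fold apart and 2.13% of those set 16-fold apart were called. The simulated means were taken over both diets, so taxa absent on high-fat diet, such as Sutterella, were simulated there as present. The recovery is thus a rough guide only. The 0 OTUs that edgeR called between genotypes on high-fat diet therefore decide little.

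The comparison of conventional with germ-free epithelium asked which transcripts go with the presence of microbes. Among 19 genes with a mean of at least 1 FPKM, 1 passed limma's test. Mettl26 (listed as 0610011F06Rik, mm10 chromosome 17, 25875500 to 25877163), a protein-coding gene, was at 16.6 ± 0.259 FPKM in conventional and 28.0 ± 1.35 FPKM in germ-free epithelium (SD, n = 2 each). Its log2 fold on the log2(FPKM + 1) scale was -0.72 ± 0.05 SE (limma adjusted p = 0.00512). The call ended with quantile normalization, where the log2 fold was -0.128 (adjusted p = 0.61), and without either germ-free library, where it was -0.769 and -0.674 (adjusted p = 0.0886 and 0.121), while leaving out a conventional library gave 5 or 4 called genes.

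All 22 genes carry symbols ending in Rik, which the list of non-coding RNAs fixed for this table takes in, although most are protein-coding genes under later names; adjusted over the list alone, limma called the same 1 of 19. Non-coding members included Snhg18 (0610007N19Rik, chromosome 15, 32240568 to 32244662), a small nucleolar RNA host gene like Snhg9, at 2.28 ± 0.638 FPKM in conventional and 4.99 ± 0.765 FPKM in germ-free epithelium (SD, n = 2 each; limma adjusted p = 0.0579). Hnf4aos, antisense to Hnf4a, lay at 1.39 ± 0.855 and 3.60 ± 0.510 FPKM (adjusted p = 0.102), and its reads cannot be told from those of Hnf4a if strand was not used. The lncRNA 0610005C13Rik lay at 37.7 ± 6.04 and 58.0 ± 0.392 FPKM (adjusted p = 0.0564), and Erg28, a sterol synthesis gene, at 59.6 ± 0.476 and 70.5 ± 0.565 FPKM (adjusted p = 0.0555). At an unadjusted p under 0.05, 7 genes differed in limma, against 8 or 13 without a conventional library, 2 or 1 without a germ-free library and 1 with quantile normalization. The 7 genes were all lower in conventional epithelium, Mettl26 among them, with log2 folds of -0.985 to -0.197. An exact test of 1 gene with 2 against 2 libraries allows no p under 0.333.

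**Figure D4:**
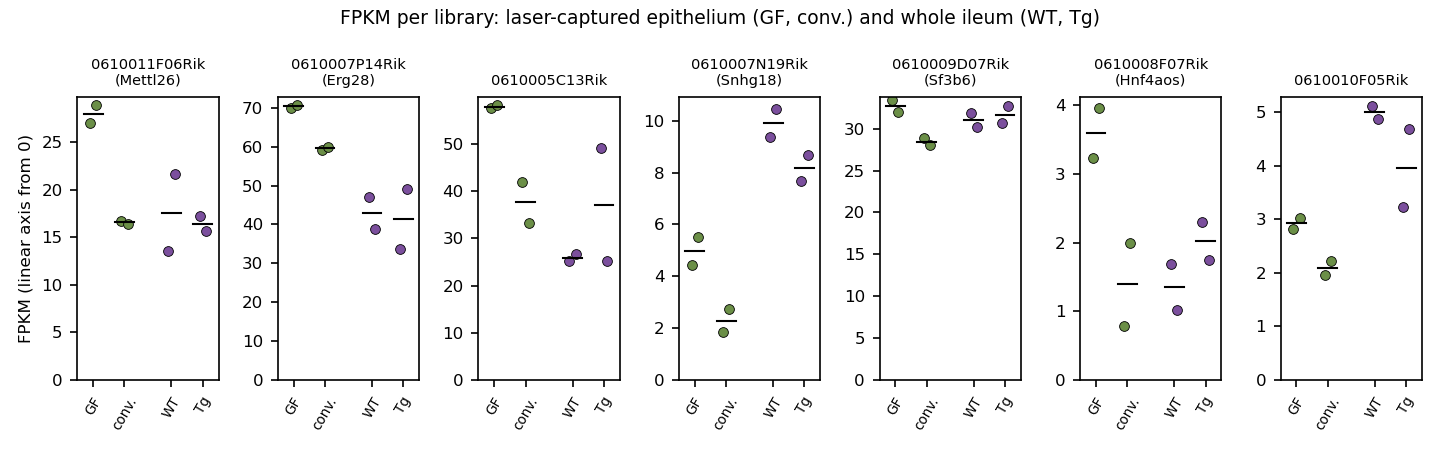
FPKM per library (linear axes from 0) of the 7 genes at an unadjusted p under 0.05 in the epithelium table, with bars at the means of 2 libraries, in germ-free (GF) and conventional (conv.) epithelium and in wild-type (WT) and transgenic (Tg) ileum. Levels are not comparable between the epithelium and ileum tables; Mettl26 averaged 28.0 and 16.6 FPKM in germ-free and conventional epithelium.

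The comparison of transgenic with wild-type ileum asked which transcripts go with added Snhg9. Of the same 19 genes, limma called 0, with 0 at an unadjusted p under 0.05. Snhg18 was at 8.18 ± 0.701 FPKM in transgenic and 9.93 ± 0.765 FPKM in wild-type ileum, and Mettl26 at 16.4 ± 1.12 and 17.6 ± 5.68 FPKM (SD, n = 2 each; limma adjusted p = 0.735 and 0.975). The lncRNA 0610005C13Rik lay at 37.2 ± 17.0 and 25.9 ± 1.05 FPKM, and Hnf4aos at 2.03 ± 0.389 and 1.36 ± 0.476 FPKM. Across the 19 genes, 13 had the same sign in both RNA comparisons (Fisher's exact p = 0.147, across genes, which are not independent replicates).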

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

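All tests of explanations in this part were chosen after the results were seen. Of 80 groups of 4 or 5 samples examined for a sample far from the others, 6 held one, where chance gives about 1 in 20. On high-fat diet, transgenic sample 5 had 30.9% Proteobacteria, against 13.8% to 17.5% in the other samples of its group, and 23.3% Helicobacteraceae, against 5.74% to 9.64%. Transgenic sample 3 on high-fat diet had 3.24% Actinobacteria, against 0.324% to 1.05%. Transgenic sample 1 on chow had 4.38% TM7, and the same 4.38% as its family F16, against 1.30% to 1.92% in the others. Wild-type sample 4 on chow had 2.70% Helicobacteraceae, against 0.516% to 0.692%.

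A signal outside the bacterial taxa was seen among OTUs with no phylum. Of 92 such OTUs, 10 aligned to the mouse genome, as mouse DNA amplified by the 16S primers would. Of 1540 assigned OTUs, 0 aligned (Fisher's exact p = 2.01e-13). An OTU that was given a named phylum could hardly align to mouse as well, so this contrast adds little to the 10 alignments. These 10 OTUs held 52 counts in 7 of 9 high-fat samples and 0 counts in the 9 chow samples (exact permutation p = 0.0034, two-sided). Wild-type sample 4 held 28 of these counts, and without it 24 counts in 6 high-fat samples remained (exact permutation p = 0.0034). The highest share was 0.0304%, so they bear little on the shares of bacteria. Which property of the high-fat samples goes with them was not tested.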

How the results depend on the processing

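Drawing counts to the smallest library, removing S24-7 from the totals and leaving out samples for the OTUs aligned to the mouse genome were chosen after the results were seen; the first 2 each gave 40 genera changed with diet (21 higher, 19 lower), against 39. Among results that answer a comparison, 534 values under an alternative kept their direction and side of the threshold or, for counts, stayed within 1.5 times, 22 changed sign, 7 counts moved further, 7 values ceased to pass and 3 began to. Among single taxa and genes 1526 kept both, 25 changed sign, 28 became and 20 ceased to be called. The count of genera changed with diet stayed at 36 to 43 in every alternative. The cause was not tested for the values below unless stated.

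DESeq2 called 35 genera with diet in wild-type samples and 8 OTUs between genotypes on high-fat diet. With no filter, edgeR called 7 OTUs between genotypes on high-fat diet and 3 for the interaction. With a total of at least 100 counts, where fewer OTUs are tested, 329 OTUs were called with diet and 273 with diet in transgenic samples. In the epithelium limma called 2 genes at a mean of at least 5 FPKM (0610011F06Rik and 0610007P14Rik), 0 with quantile normalization (1 unadjusted) and 0 to 5 with 1 library left out, where the lone library is assumed to vary like the other group. Of genes past the threshold in either RNA table, 1 of 1 had the same sign in both.

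Values that changed sign were those of differences that passed no test. With quantile normalization 0610011F06Rik in the ileum was at 0.11 (log2). Chao1 gave differences of 13.1 and -23.3 between genotypes on chow and high-fat diet where the Shannon index had the other sign, and the Simpson index gave -0.0053 for diet in wild-type and -0.00188 over both genotypes. With no filter, Bacteroides was at 0.0495 and Lactobacillus at 0.10 for diet (log2). With 1 sample left out, the Shannon index differed by -0.104 to 0.0847 and by -0.028 to 0.209 between genotypes on chow and high-fat diet, and by -0.0212 to 0.204 with diet in wild-type. The observed OTUs differed by -34.2 to 33.5, by -48.9 to 7.14, and by -16.5 to 48.5 with diet in transgenic samples. The phylum TM7 share and the family F16 share ranged from -0.151 to 0.342 points, the family Lactobacillaceae share from -1.05 to 3.91 points, Parabacteroides from -0.33 to 0.43 (log2), and in the ileum 0610005C13Rik from -0.0417 to 0.90 and 0610011F06Rik from -0.38 to 0.26 (log2).

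In no comparison did every same-numbered pair correlate above 0.1, so the numbers were not taken to pair samples: of 9 same-numbered pairs across diets, 1 had a correlation of deviations above 0.1 (range -0.258 to 0.326 in wild-type, -0.223 to -0.0514 in transgenic samples), and across genotypes 3 of 4 did on chow (-0.0729 to 0.281) and 3 of 4 on high-fat diet (0.0563 to 0.624). This rule is strict and cannot show that the samples are unpaired. Same-numbered samples had the smaller mean Bray-Curtis distance in every comparison, as given below. With the number as a block, the Bray-Curtis share of diet stayed at 0.698 and 0.660 with exact p of 0.125 and 0.0625, the smallest that 4 and 5 pairs allow, and 0 phyla and 0 families passed in transgenic samples for the same reason. Over both genotypes, the counts of phyla and of families changed with diet stayed within 1.5 times in all 20 alternatives, the block included. Under the block the Shannon index difference between genotypes on chow was 0.0538, the log2 fold was -0.0793 for Parabacteroides: high-fat diet versus chow, and edgeR called 39 genera and 495 OTUs with diet; limma called 0 genes in the ileum (1 unadjusted). For the epithelium alone no paired analysis was possible, because its columns, numbered 2 and 3 where the labels have 1 and 2, cannot be matched to samples and were given no number. DESeq2 on RNA was not run, as FPKM are not counts, nor the authors' thresholds, as the tables hold no test. Depth limits statements on taxa under about 0.00472% of counts.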

Other observations

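The tests of Mucispirillum, Turicibacter and SMB53 and the counts over other splits of the samples were chosen or described only after the results were seen.

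Smaller families also changed between diets in the exact permutation test over both genotypes. Odoribacteraceae was higher by 1.06 percentage points (adjusted p = 0.000748), Streptococcaceae by 0.902 (adjusted p = 0.000356) and unclassified Bacteroidales by 2.78 (adjusted p = 0.000356) on high-fat diet. Coriobacteriaceae fell by 1.02 points (adjusted p = 0.0265), Paraprevotellaceae by 1.64 (adjusted p = 0.00208) and Alcaligenaceae, the family of Sutterella, fell by 2.25 (adjusted p = 0.000356).

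Mucispirillum stood at 3.21% ± 0.992 (SD, n = 5) in transgenic and 0.633% ± 0.514 (SD, n = 4) in wild-type feces on high-fat diet. Closure of the shares makes a taxon seem higher because others fell. The centred log-ratio of Mucispirillum, taken against the mean log count of the genera tested, had a log2 fold of 2.73 ± 0.89 SE. This argues against closure through a few abundant taxa alone. It cannot decide on a fall of most genera, which would raise the log-ratio as well. Chance among the genera tested stays open: 56 of all possible splits of the 9 samples (44.4%) held a genus with an exact p as small. The interaction of genotype and diet for Mucispirillum had an edgeR p of 0.0244 (adjusted p = 0.885). A genotype effect may still be present, and was not separated from chance here. Nor could it be told from a cage or litter shared within a genotype, which the labels do not give.

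On high-fat diet, Turicibacter and SMB53, a genus of Clostridiaceae, had their higher counts in different samples. Turicibacter had 961, 649, 2 and 3 counts in wild-type samples 1 to 4 and 393, 76, 0, 2 and 1 counts in transgenic samples 1 to 5, while SMB53 had 0, 0, 588 and 32, and 0, 0, 489, 10 and 43. Unclassified Peptostreptococcaceae had counts in the same samples as SMB53, with 0, 0, 1371 and 84, and 0, 0, 935, 28 and 108. Unclassified Clostridiaceae were highest in the samples with most Turicibacter, with 2503, 1755, 151 and 14, and 898, 108, 112, 41 and 22. Library depth is argued against, since the lowest SMB53 share seen was 2.97 times the highest floor of the samples without it (exact Poisson 95% interval 1.42 to 5.46). Shared numbers may mark a shared cage, litter or day; same-numbered samples of both genotypes had a mean Bray-Curtis distance of 0.401 against 0.448 for other pairs (one-sided exact p = 0.183), and on chow 0.218 against 0.286 (one-sided exact p = 0.0333). Across diets they were 0.747 against 0.761 in transgenic (one-sided exact p = 0.0583) and 0.681 against 0.697 in wild-type samples (one-sided exact p = 0.125), so same-numbered samples were closer in all 4 tests, with 1 p under 0.05. Deviations of genus counts correlated above 0.1 in 3 of 4 same-numbered pairs on high-fat diet (0.0563 to 0.624) and in 3 of 4 on chow (-0.0729 to 0.281), so a shared origin stays open. No biological explanation was tested.

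For diet, chance was an unlikely source of the counts of calls if the samples are independent, but 35 or 100 splits cannot exclude it. The real split alone gave as many calls, 1 of 100 splits for genera over both genotypes (39 against at most 16 in the others), 1 of 35 in wild-type (21 against 1) and 1 of 100 in transgenic samples (31 against 4). For OTUs it was likewise 1 of 100 (527 against 122), 1 of 35 (389 against 0) and 1 of 100 (424 against 4). For genotype on chow, genotype on high-fat diet and the interaction, where edgeR called 0 (1, 3 and 1 genera and 23, 45 and 35 OTUs unadjusted), the count of 100 of 100 splits with as many is fixed by the 0 and decides nothing; the other splits gave at most 7, 7 and 3 genera and 4, 22 and 4 OTUs. At the unadjusted p, 89, 68 and 95 of 100 splits gave as many genera as the real one and 93, 60 and 91 as many OTUs. Chance thus stays open there, with counts this large common among the splits. The split with 22 OTUs exchanged the labels of wild-type samples 1 and 2 and transgenic samples 3 and 5 on high-fat diet. It thus set wild-type samples 3 and 4 and transgenic samples 3 and 5, the samples with the most SMB53 counts, apart from the others. It may reflect a structure of these samples other than genotype, but it was picked as the highest of 100 and no test of it was run.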
